A study of Mus musculus with 6 samples.

How the data were processed

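Messenger RNA of mouse epididymal white adipose tissue was sequenced in 6 libraries, 2 per diet group. The deposited table gives raw whole-number counts per gene and library, per the file headers. It also gives RPKM (reads scaled by gene length in kilobases and by library size), which the authors computed from the counts, the gene length and the library total, and the library total implied by the deposited RPKM matches the sum of counts to within a relative 1e-6 in 100% of genes with more than 50 counts, in each library. A further deposited column, Length, holds the gene length in bases that the authors used (unit: other). The tools listed per the submitters' processing notes, without roles, are bcl2fastq, HISAT2 2.1.0 and HTSeq, with genome build mm10; the strand setting and the annotation release are not given in the sources used here. The table holds 48897 genes, of which 27 had symbols turned into dates and were restored by Entrez ID. Of 40020 genes with an Entrez ID, 39064 were found in the RefSeq annotation of mm10, 99.8% of them on the same chromosome with the start within 500 kb.

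Total counts ran from 41091012 to 49230161 per library, so that a count of 0 allows a level of up to 0.0537 to 0.0754 TMM-adjusted CPM (3 counts). The spread between libraries of a group exceeded counting noise, with a chi-square per degree of freedom of 861.8 in F-L, 225.5 in F-H and 59.7 in F-H-L. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The design, fixed before the data were examined, named limma on log2(RPKM + 1) as the test unless raw counts were deposited, in which case edgeR on the counts was to be used; as counts were deposited, edgeR was used. filterByExpr kept 22289 genes, TMM factors were 1.08, 1.16, 0.922, 0.986, 0.968 and 0.902, and 1 quasi-likelihood model with a term per group was fitted to all 6 libraries (3 residual degrees of freedom, median prior degrees of freedom 2.6, common dispersion 0.398, biological coefficient of variation 0.631). Adjusted p is by Benjamini-Hochberg over the genes of a comparison, called under 0.05, and the SE of a log2 fold change is its size over the square root of the F statistic. All 3 comparisons between groups were made, and tests are two-sided.

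The 30 gene lists were fixed before the data were examined, with 532 members found and 1, Plin2, not analysed here. They were tested with camera (preset inter-gene correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the 30 lists of a comparison, and again with an estimated correlation and with fry. Named genes followed a rule set in advance: the 6 largest rises and falls past the test with a group mean RPKM of at least 5, the 3 members with the smallest p of each list that moved, at most 2 members past the test of any other list, and 8 genes always named; some members that met it are not reported here, but stay in the list tests and in the totals of values. 6 further lists (fresh testis and epididymis lists, Leydig cell, multiciliated cell, lysosome and complement genes) were written after reproductive-tract genes had been seen. Alternatives were limma on RPKM with pseudocounts of 1, 0.5 and 0.1 and on TPM, no filter or an RPKM filter of 5, quantile normalization, median-ratio factors, robust empirical Bayes, a replicate block, the 2 groups compared alone, each library left out, DESeq2 and other thresholds. Scaling to the adipocyte list, the epididymis score (mean log2 CPM of that list) as covariate, and a crossed pairing of replicate numbers were added after the data had been examined. The epididymis score differed between groups, so as covariate it may remove diet differences too, and it tests nothing for its own list. Simulations used the gene-wise dispersions of the fit to all 6 libraries for every comparison, so the F-L spread also entered F-H-L against F-H. In report order, edgeR found 34.4%, 18.4% and 27.8% of genes changed 16-fold, 0% changed 4-fold, and 1, 1 and 2 false calls. Camera found a list of 20 genes shifted 4-fold each time and 0 of 20 random lists. Random lists are not co-expressed, so the preset correlation was untested. Replicate numbers did not pair libraries: deviations of equally numbered ones correlated at 0.024, -0.138 and -0.019 across genes. The main results used all libraries.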

Results

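The series asked how cycles of diet switching affect metabolic homeostasis. It measured the messenger RNA of epididymal white adipose tissue, the visceral fat depot attached to the epididymis, in C57BL/6 mice aged 35 weeks. Diets began at 6 weeks of age and drew 10% of calories from fat (low-fat) or 60% (high-fat). Group F-L is read as continuous low-fat feeding, F-H as continuous high-fat feeding, and F-H-L as 9 weeks of high-fat feeding followed by 10 cycles of 1 low-fat week and 1 high-fat week. The labels tie these codes to the diets by their letters only, and a cycle as described ended in a high-fat week. Each group had 2 libraries, numbered replicate 1 and replicate 2. The labels do not say that the libraries came from separate mice, so the p-values measure the spread between libraries, which may be technical. Total counts were 41091012 and 48305365 in F-L, 49230161 and 41926916 in F-H, and 45308438 and 44090618 in F-H-L. Across genes, which are not independent replicates, log2 CPM (counts scaled to TMM-adjusted library size) of the 2 libraries of a group correlated at r = 0.815 in F-L, 0.948 in F-H and 0.970 in F-H-L. The first principal component held 56.0% of the variance and placed F-L and F-H at its ends, and the second (21.6%) set the F-L libraries apart from each other.

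Transcripts of the male reproductive tract, which adjoins this fat depot, differed widely between libraries. The 19 epididymis epithelium markers, such as the sperm-coating protein gene Crisp1, took 2.92% (95% Wilson interval 2.915 to 2.925) of the counts of F-L replicate 1 and 0.577% (0.575 to 0.579) of F-L replicate 2. The same genes took 0.000376% (0.000325 to 0.000434) and 0.0522% (0.0515 to 0.0529) in F-H, and 0.254% (0.252 to 0.255) and 0.244% (0.242 to 0.245) in F-H-L. The 14 testis germ cell markers, such as the protamine gene Prm2, were highest in F-L replicate 2 at 0.699% (0.697 to 0.702), against 0.0798% (0.0789 to 0.0806) in F-L replicate 1. They took 0.000483% (0.000426 to 0.000549) and 0.00124% (0.00114 to 0.00135) in F-H, and 0.0124% (0.0121 to 0.0127) and 0.0139% (0.0136 to 0.0143) in F-H-L. The 20 adipocyte identity and hormone genes had a median of 103 CPM in F-L replicate 1 and 944 CPM in F-L replicate 2, 633 and 694 CPM in F-H, and 1466 and 1739 CPM in F-H-L. These intervals cover counting error only.

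**Figure D1:**
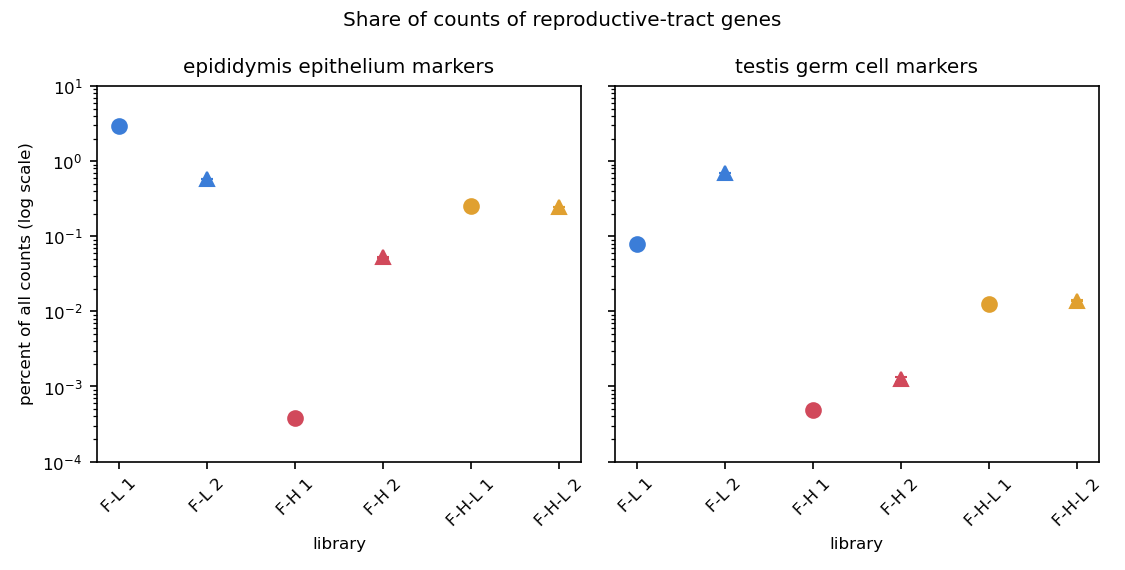
Percent of all counts (vertical log axis) taken by epididymis epithelium markers and testis germ cell markers (panels) in each of the 6 libraries (horizontal axis), each point being 1 library with its 95% Wilson interval. The epididymis share runs from 0.000376% in F-H replicate 1 to 2.92% in F-L replicate 1.

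The comparison of F-H with F-L addressed what continuous high-fat feeding changed in this fat. Macrophage markers rose (20 of 20, 8 past the test), though not by camera with an estimated correlation (adjusted p = 0.616). Trem2, a lipid-sensing receptor of macrophages, was at 413 and 417 CPM in the 2 F-H libraries and 7.57 and 5.87 CPM in F-L. Its log2 fold change was 5.95 ± 0.35 (SE, n = 2 per group, edgeR adjusted p = 0.0448). Itgax, which encodes the integrin CD11c, was at 290 and 230 CPM against 2.01 and 3.63 CPM, and Mmp12, the macrophage elastase, at 672 and 1233 CPM against 0.541 and 2.26 CPM. Epididymis and testis transcripts were among the genes that fell, such as the sperm tail gene Odf1 at 0.353 and 0.509 CPM in F-H and 256 and 532 CPM in F-L.

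Numbers in brackets after a gene are its log2 fold change ± SE in the comparison described, from the edgeR fit with n = 2 libraries per group, and the median of a list is that of its members' log2 fold changes. Camera's adjusted p is given with a preset and with an estimated correlation between genes. Of 22289 genes tested, 193 passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 137 higher and 56 lower in F-H, and 6507 had an unadjusted p under 0.05. The largest named rises were Mmp12 (9.40 ± 1.08), Rgs1 (7.28 ± 0.79), Clec4d (7.05 ± 0.90), Gpnmb (6.63 ± 0.59), Itgax (6.53 ± 0.44) and Glipr1 (6.18 ± 0.67), of which Rgs1 is a signalling regulator of leukocytes, Clec4d a lectin of myeloid cells and Gpnmb a glycoprotein of lipid-laden macrophages. The largest named falls included Pate2 (-12.25 ± 1.26), BC048679 (-12.12 ± 1.51), Spint3 (-11.19 ± 1.46) and Defb28 (-10.61 ± 1.41), of which Spint3 is a protease inhibitor gene and Defb28 a beta-defensin gene. Bsph2, a sperm-binding protein gene, had 0 and 3 counts in the F-H libraries and 8976 and 1996 in the F-L libraries. The beta-defensin gene Defb38 had 0 and 1 counts in F-H and 4942 and 955 in F-L, and the F-H counts are too few for a stable fold change. In genome build mm10, the deposited spans were Trem2 (Entrez 83433, chromosome 17, 48346401 to 48352276), Itgax (Entrez 16411, chromosome 7, 128129530 to 128150657), Mmp12 (Entrez 17381, chromosome 9, 7344397 to 7360461) and Odf1 (Entrez 18285, chromosome 15, 38219203 to 38226735). The gene calls depended on the fit: edgeR called 0 genes with median-ratio factors, robust empirical Bayes, the 4 libraries of both groups alone or the epididymis score as covariate, and 0 without any 1 of the F-H and F-H-L libraries. Unadjusted p was under 0.05 for 2159 to 6429 genes in those fits. edgeR called 4474 genes without F-L replicate 1, 5799 without F-L replicate 2 and 6025 with no low-count filter, and DESeq2 called 6035, 2193 of them higher. limma called 871 genes on log2(RPKM + 1), 508 of them higher, and 1447 after quantile normalization, which moved the median of all genes from -0.12 to 0.16. Scaling each library to its adipocyte genes gave 3526 calls, 114 of them higher, and a median log2 fold change of all genes of -1.795. This lowers the medians of all lists, by unequal amounts, and where it ended a list call that is said.

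Macrophage lists rose, beside the epididymis and testis shares given above, which were lower in both F-H libraries. Macrophage markers rose (median 4.24, camera adjusted p = 8.8e-17 preset, 0.616 estimated). Itgax (6.53 ± 0.44), Tyrobp (4.71 ± 0.44) and Ms4a7 (4.66 ± 0.48), of which Tyrobp encodes an immune receptor adaptor and Ms4a7 a macrophage membrane protein, were named, of 20 members with 20 positive, 8 past the test over all genes and 18 adjusted over the list alone. The macrophage median was 4.95 without F-L replicate 2, 3.05 with adipocyte scaling and 3.02 with the epididymis covariate. Adgre1, which encodes the macrophage antigen F4/80, was at 1310 and 562 CPM against 11.6 and 34.1 CPM and did not pass over all genes (log2 fold change 5.35 ± 0.82, edgeR adjusted p = 0.0539). Lipid-associated macrophage genes rose (median 4.30, camera adjusted p = 4.3e-16 preset, 0.0838 estimated). Trem2 (5.95 ± 0.35), Gpnmb (6.63 ± 0.59) and Lgals3 (4.30 ± 0.38), where Lgals3 encodes galectin-3, were named, of 17 members with 17 positive, 8 past the test over all genes and 16 adjusted over the list alone. The lipid-associated macrophage median was 2.56 with adipocyte scaling. By fry, which tests whether the genes of a list move one way on balance, this list alone passed (adjusted p = 9.5e-04), and no list passed camera with an estimated correlation. Cytokine and chemokine genes rose (median 3.57, camera adjusted p = 1.3e-10 preset, 0.616 estimated). Ccl3 (5.56 ± 0.74), Tnf (4.19 ± 0.86) and Ccl2 (3.30 ± 1.14), of which Ccl3 and Ccl2 encode leukocyte attractants, were named, of 24 members with 24 positive, 1 past the test over all genes and 19 adjusted over the list alone. The cytokine median was 4.66 without F-L replicate 2, 2.52 without F-H replicate 1, 4.29 without F-H replicate 2, 2.64 with adipocyte scaling, 1.89 with the epididymis covariate and 2.33 to 2.94 with limma on RPKM.

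Lists of lymphocytes and other immune cells rose as well. T and NK cell markers rose (median 3.67, camera adjusted p = 5.0e-07 preset, 0.616 estimated). Klrb1c (3.72 ± 0.90) and Prf1 (5.96 ± 1.47) were named, of 20 members with 20 positive, 0 past the test over all genes and 17 adjusted over the list alone. The T and NK cell median was 1.82 without F-H replicate 1, 4.50 without F-H replicate 2, 2.29 with adipocyte scaling and 1.79 to 2.59 with limma on RPKM, and the call ended with the epididymis covariate (median 0.76, adjusted p = 0.0506). MHC class II and dendritic cell genes rose (median 3.40, camera adjusted p = 5.7e-07 preset, 0.616 estimated). H2-DMb1 (4.41 ± 0.69), Batf3 (3.16 ± 0.67) and Ciita (4.96 ± 1.07) were named, of 17 members with 16 positive, 0 past the test over all genes and 14 adjusted over the list alone (1 more in the other direction). The MHC class II median was 4.03 without F-L replicate 2, 1.93 without F-H replicate 1, 4.23 without F-H replicate 2, 2.15 with adipocyte scaling, 1.13 with the epididymis covariate and 2.33 to 2.70 with limma on RPKM. B cell and plasma cell markers rose (median 2.98, camera adjusted p = 2.1e-06 preset, 0.616 estimated). Cd22 (5.18 ± 0.87), Jchain (4.29 ± 0.92) and Ighd (2.85 ± 0.66) were named, of 16 members with 16 positive, 0 past the test over all genes and 9 adjusted over the list alone. The B cell median was 2.04 without F-H replicate 1, 1.48 with adipocyte scaling and 1.40 with the epididymis covariate. Mast cell markers rose (median 3.82, camera adjusted p = 7.2e-05 preset, 0.616 estimated). Mcpt4 (3.92 ± 0.54), Cpa3 (3.97 ± 0.55) and Cma1 (4.01 ± 0.58), all mast cell proteases, were named, of 10 members with 9 positive, 0 past the test over all genes and 6 adjusted over the list alone. The mast cell median was 2.35 with adipocyte scaling. Interferon response genes rose (median 1.47, camera adjusted p = 3.4e-05 preset, 0.616 estimated). Oas1a (2.76 ± 0.70) and Oasl2 (2.14 ± 0.61) were named, of 19 members with 18 positive, 0 past the test over all genes and 0 adjusted over the list alone. The interferon response median was 2.20 without F-L replicate 2, 0.73 without F-H replicate 1 and 0.16 with adipocyte scaling, and the call ended with the epididymis covariate (median 0.17, adjusted p = 0.281).

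Matrix, stromal and growth lists were also higher in F-H. Extracellular matrix genes rose (median 1.90, camera adjusted p = 8.9e-13 preset, 0.616 estimated). Timp1 (3.17 ± 0.49), Bgn (2.23 ± 0.35), Mmp2 (3.64 ± 0.60) and Col1a1 (1.93 ± 0.33), which encode a protease inhibitor, a proteoglycan, a gelatinase and a collagen chain, were named, of 26 members with 26 positive, 0 past the test over all genes and 19 adjusted over the list alone. The extracellular matrix median was 3.10 without F-L replicate 2 and 0.89 with adipocyte scaling. Adipose progenitor markers rose (median 1.29, camera adjusted p = 4.9e-04 preset, 0.616 estimated). Thy1 (1.87 ± 0.37), Pdgfrb (1.80 ± 0.39) and Pdgfra (1.11 ± 0.24) were named, of 14 members with 12 positive, 0 past the test over all genes and 6 adjusted over the list alone (1 more in the other direction), and Pdgfra turned negative with adipocyte scaling. The adipose progenitor median was 2.00 without F-L replicate 2 and 0.01 with adipocyte scaling. Immediate early genes rose (median 1.66, camera adjusted p = 6.9e-08 preset, 0.616 estimated). Junb (2.25 ± 0.24), Zfp36 (1.86 ± 0.23) and Atf3 (5.44 ± 0.69), which respond fast to stimulation, were named, of 18 members with 18 positive, 3 past the test over all genes and 11 adjusted over the list alone. The immediate early median was 0.25 with adipocyte scaling. Cell proliferation genes rose (median 0.76, camera adjusted p = 1.5e-04 preset, 0.616 estimated), though the median turned to -0.06 with adipocyte scaling. Mcm6 (1.93 ± 0.28), Mcm3 (1.56 ± 0.29) and Pcna (1.61 ± 0.34), which act in DNA replication, were named, of 23 members with 16 positive, 0 past the test over all genes and 3 adjusted over the list alone, and Mcm3 turned negative with adipocyte scaling. The cell proliferation median was 1.51 with quantile normalization, 1.37 with a replicate block and 3.18 without F-L replicate 2, and the call ended without F-L replicate 1 (median 0.65, adjusted p = 0.157) and with the epididymis covariate (median 0.39, adjusted p = 0.182). Endothelial markers rose (median 0.72, camera adjusted p = 0.0266 preset, 0.753 estimated). Eng (1.46 ± 0.52), Pecam1 (1.02 ± 0.72) and Tek (0.83 ± 0.62) were named, of 12 members with 12 positive, 0 past the test over all genes and 0 adjusted over the list alone, and Tek turned negative with adipocyte scaling. The endothelial median was 1.86 without F-L replicate 2, and the call ended without F-L replicate 1 (median 0.17, adjusted p = 0.392), without F-H replicate 2 (median 0.30, adjusted p = 0.157), with limma on RPKM (medians of 0.54 to 0.65, adjusted p of 0.113 to 0.121), with the RPKM filter of 5 (median 0.45, adjusted p = 0.186), with quantile normalization (median 0.77, adjusted p = 0.168), with limma on TPM (median 0.68, adjusted p = 0.142) and with adipocyte scaling (median -0.30, adjusted p = 0.0953).

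Lists of fat metabolism also rose, beside an adipocyte median of 103 CPM in F-L replicate 1. Fatty acid oxidation genes rose (median 1.05, camera adjusted p = 2.3e-05 preset, 0.616 estimated), though the median turned to -0.23 with adipocyte scaling. Cpt1a (1.97 ± 0.33), Acadvl (1.09 ± 0.37) and Hadha (0.94 ± 0.34), where Cpt1a encodes the rate-limiting carnitine transferase, were named, of 19 members with 17 positive, 0 past the test over all genes and 1 adjusted over the list alone, and Acadvl and Hadha turned negative with adipocyte scaling. The fatty acid oxidation median was 1.84 without F-L replicate 2. Thermogenic adipocyte genes rose (median 1.62, camera adjusted p = 0.00201 preset, 0.616 estimated). Ucp1 (5.73 ± 0.98), Tmem26 (2.31 ± 0.69) and Otop1 (3.82 ± 1.19) were named, of 14 members with 12 positive, 0 past the test over all genes and 1 adjusted over the list alone. The thermogenic adipocyte median was 2.81 with quantile normalization, 0.90 without F-L replicate 1, 2.97 without F-L replicate 2 and 0.88 with adipocyte scaling. Ucp1, the uncoupling protein gene of brown fat, was at 2.09 and 5.77 CPM in F-H and 0.0901 and 0.0537 CPM in F-L. Adipocyte identity and hormone genes rose (median 0.54, camera adjusted p = 0.0379 preset, 0.848 estimated). Mrap (1.72 ± 0.90), Cd36 (1.96 ± 1.12) and Pparg (1.33 ± 0.80) were named, of 20 members with 16 positive, 0 past the test over all genes and 0 adjusted over the list alone. The adipocyte median was 3.04 without F-L replicate 2, and the test turned without F-L replicate 1, and the call ended without F-L replicate 1 (median -0.31, adjusted p = 0.875), with limma on RPKM (medians of 0.98 to 1.04, adjusted p of 0.0952 to 0.106), with the RPKM filter of 5 (median 0.26, adjusted p = 0.186), with quantile normalization (median 0.998, adjusted p = 0.485), with limma on TPM (median 1.10, adjusted p = 0.142) and with the epididymis covariate (median 0.30, adjusted p = 0.609). The hormone genes Lep (1.53 ± 1.09) and Adipoq (0.45 ± 1.07) did not pass, and Adipoq turned to -0.45 without F-L replicate 1. Lipolysis genes rose (median 0.70, camera adjusted p = 0.0121 preset, 0.753 estimated). Prkaca (0.69 ± 0.34) and Hcar2 (1.84 ± 1.01) were named, of 16 members with 14 positive, 0 past the test over all genes and 0 adjusted over the list alone, and Prkaca turned negative with adipocyte scaling. The lipolysis median was 2.40 without F-L replicate 2 and 0.08 with adipocyte scaling, and the call ended without F-L replicate 1 (median -0.02, adjusted p = 0.671), with limma on RPKM (medians of 0.87 to 0.90, adjusted p of 0.0502 to 0.0521), with the RPKM filter of 5 (median 0.43, adjusted p = 0.120), with quantile normalization (median 0.99, adjusted p = 0.128), with limma on TPM (median 0.998, adjusted p = 0.0795) and with the epididymis covariate (median 0.48, adjusted p = 0.262). De novo lipogenesis was not called (median -0.29, camera adjusted p = 0.975), and the fatty acid synthase gene Fasn (-0.22 ± 0.73) turned to 1.11 without F-L replicate 2. Camera called de novo lipogenesis higher without F-L replicate 2 (median 1.44, adjusted p = 0.0213).

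Reproductive-tract lists fell in F-H. Testis germ cell markers fell (median -8.90, camera adjusted p = 4.2e-10 preset, 0.616 estimated). Odf1 (-9.83 ± 0.65), Smcp (-8.72 ± 0.98) and Tssk6 (-5.83 ± 0.83) were named, of 14 members with 14 negative, 2 past the test over all genes and 14 adjusted over the list alone. The testis germ cell median was -7.35 with quantile normalization, -9.84 without F-L replicate 1, -5.41 without F-L replicate 2, -8.14 without F-H replicate 1, -10.03 without F-H replicate 2 and -7.67 to -6.14 with limma on RPKM. With the 1 member without counts in F-H set to its bound, the testis median was -8.76. Epididymis epithelium markers fell (median -4.17, camera adjusted p = 4.9e-04 preset, 0.654 estimated). Crisp4 (-10.59 ± 1.54), Abcb5 (-11.08 ± 1.84) and Rnase9 (-9.82 ± 1.84) were named, of 19 members with 12 negative, 0 past the test over all genes and 6 adjusted over the list alone. The epididymis epithelium median was -9.78 with the RPKM filter of 5, -3.12 with quantile normalization, -5.50 with a replicate block, -4.97 without F-L replicate 2, -11.17 without F-H replicate 2, -6.79 with adipocyte scaling and -7.81 to -5.63 with limma on RPKM, and the call ended without F-L replicate 1 (median -1.69, adjusted p = 0.228), without F-H replicate 1 (median -3.14, adjusted p = 0.222) and with the epididymis covariate (median 1.03, adjusted p = 0.393). That covariate tests nothing here. Neutrophil markers were not called (median -0.32, camera adjusted p = 0.771) but held 1 gene that fell, Ltf (-8.66 ± 0.99), at 726 and 372 CPM in F-L, whose product lactoferrin reproductive epithelia also secrete. Cholesterol synthesis, not called (median -0.33, camera adjusted p = 0.301), held 1 gene that fell, the squalene synthase gene Fdft1 (-2.92 ± 0.29), whose span overlaps that of the lysosomal protease gene Ctsb. The other lists not called were insulin action, both oxidative phosphorylation lists, branched-chain amino acid breakdown, mesothelial and muscle markers, the circadian clock and ER stress (camera adjusted p of 0.121 to 0.990). Of these, camera called insulin action higher without F-L replicate 2 (median 0.92, adjusted p = 0.00329) and with no low-count filter or without F-H-L replicate 1 (medians of 0.28 to 0.30, adjusted p of 0.0407 to 0.0498), branched-chain amino acid breakdown higher without F-L replicate 2 (median 0.53, adjusted p = 0.00552), nuclear-encoded oxidative phosphorylation higher without F-H replicate 2 (median 0.31, adjusted p = 0.0290), ER stress higher without F-L replicate 1 (median 0.48, adjusted p = 0.0345), mitochondrially encoded transcripts lower with quantile normalization (median -0.70, adjusted p = 0.0358), and mesothelial markers lower without F-H replicate 2 (median -7.56, adjusted p = 1.5e-06) and with adipocyte scaling (median -1.27, adjusted p = 0.0121). Strand use in the counting is not given in the sources used here, so genes that overlap others are uncertain: Fdft1 and Ctsb, Glipr1 and Krr1, Pate2 with Pate3 and Pate4, Ccl3 and Ccl4, Tssk6 and Ndufa13, Timp1 and Syn1, Ciita and Dexi, Eng and Fpgs, Hadha and Gareml, Adgre1 and LOC102636666. Members of the beta-defensin and Pate families are uncertain for their shared sequence.

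**Figure D2:**
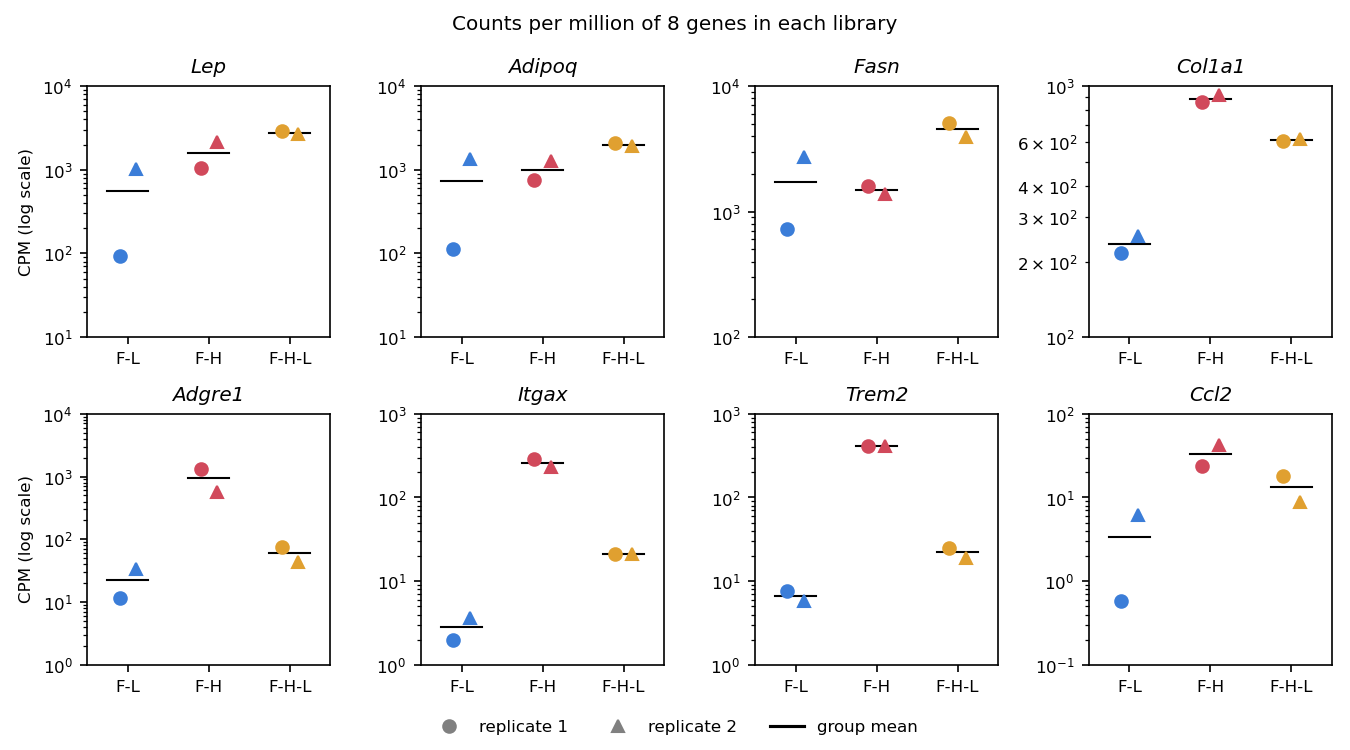
CPM (vertical log axes) of single genes in the 6 libraries, by group (horizontal axes), with points for libraries and lines for the mean of the 2 libraries. Lep lies at 93.7 CPM in F-L replicate 1 and 1018 CPM in F-L replicate 2.

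**Figure D3:**
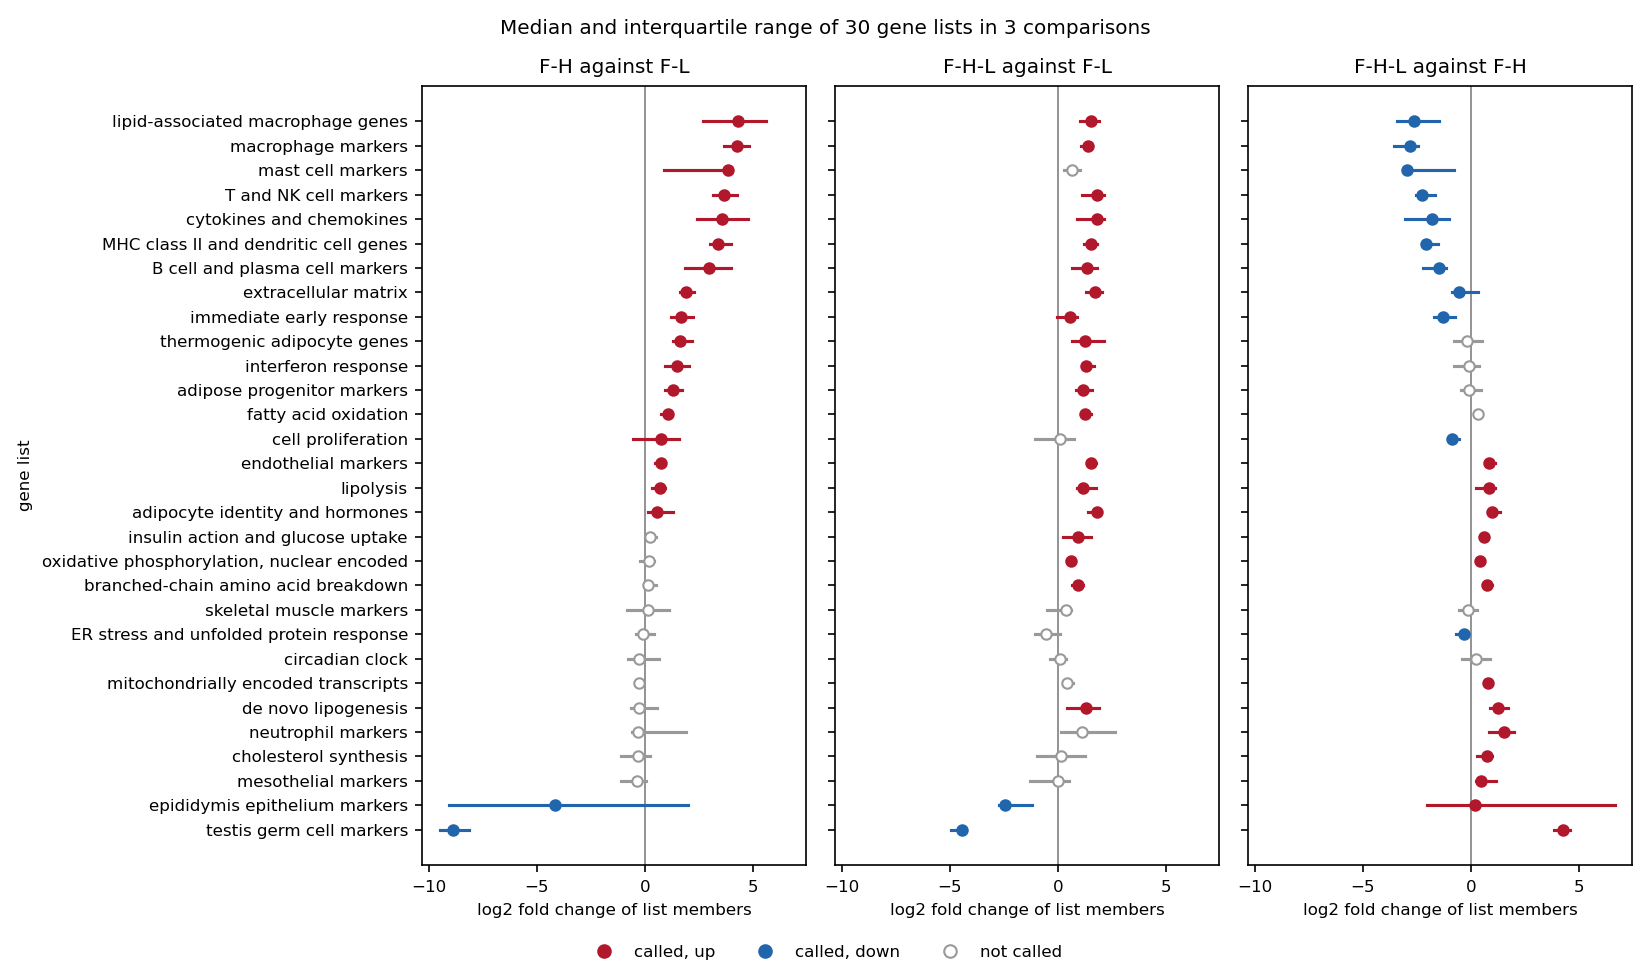
Median log2 fold change (points) and interquartile range (lines) of the members of 30 fixed gene lists (vertical axis) in the 3 comparisons (panels), coloured by the camera call with a preset correlation. The numbers of lists called are 19, 21 and 24 in the order of the text.

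The comparison of F-H-L with F-L addressed what differed from lean feeding after repeated diet cycles. Fat metabolism, macrophage, matrix and endothelial lists rose in the cycled group by camera with a preset correlation, while no single gene passed and 0 of the 21 list calls held with an estimated correlation (smallest adjusted p 0.227). Adipocyte scaling, which lowered the median of all genes to -2.999, turned the medians of these lists negative, but camera, which compares a list with other genes, still called 15 of the 18 lists higher (the adipocyte list apart). Itgax was at 20.9 and 21.0 CPM in F-H-L and 2.01 and 3.63 CPM in F-L (log2 fold change 2.89 ± 0.38, n = 2 per group), and Col6a1, a collagen VI gene, at 1086 and 1064 CPM against 178 and 331 CPM. Mgll, a lipase gene, was at 1476 and 2114 CPM against 502 and 715 CPM, and the leptin gene Lep at 2893 and 2640 CPM against 93.7 and 1018 CPM. edgeR called 0 of 22289 genes (smallest adjusted p 0.274, 3975 with an unadjusted p under 0.05), and DESeq2 called 2444, 590 higher and 1854 lower. edgeR called 2084 genes (180 higher) without F-L replicate 1, 3508 (2236 higher) without F-L replicate 2, and 3910 with no low-count filter. With adipocyte scaling it called 6290, 6 of them higher. Median-ratio factors moved the median of all genes from -0.09 to -0.21. The count of members past the test over all genes was 0 for every list, so the counts below are those adjusted over the list alone and genes are described by their values.

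Adipocyte lists rose, beside the adipocyte median of 103 CPM and the high epididymis share of F-L replicate 1. Adipocyte identity and hormone genes rose (median 1.81, camera adjusted p = 6.7e-07 preset, 0.473 estimated). Mrap (2.65 ± 0.93), Slc2a4 (1.57 ± 0.63), Cebpa (1.94 ± 0.79), Lep (2.32 ± 1.12) and Adipoq (1.44 ± 1.09) were named, of 20 members with 20 positive, 0 adjusted over the list alone. The adipocyte median was 0.85 without F-L replicate 1 and 4.15 without F-L replicate 2. De novo lipogenesis genes rose (median 1.30, camera adjusted p = 1.1e-04 preset, 0.473 estimated), though the median turned to -0.69 with adipocyte scaling. Agpat2 (2.33 ± 0.61), Slc25a1 (1.98 ± 0.67), Gpd1 (1.82 ± 0.62) and Fasn (1.38 ± 0.75) were named, of 18 members with 16 positive, 0 adjusted over the list alone, and Slc25a1, Gpd1 and Fasn turned negative with adipocyte scaling. The de novo lipogenesis median was 2.64 without F-L replicate 2. Lipolysis genes rose (median 1.15, camera adjusted p = 5.8e-06 preset, 0.473 estimated), though the median turned to -0.74 with adipocyte scaling. G0s2 (2.31 ± 0.60), Prkaca (1.13 ± 0.34) and Mgll (1.56 ± 0.50) were named, of 16 members with 16 positive, 0 adjusted over the list alone, and Prkaca and Mgll turned negative with adipocyte scaling. The lipolysis median was 0.54 without F-L replicate 1 and 3.21 without F-L replicate 2. Insulin action and glucose uptake genes rose (median 0.93, camera adjusted p = 4.6e-04 preset, 0.473 estimated), though the median turned to -1.66 with adipocyte scaling. Gys1 (1.44 ± 0.36), Akt2 (1.10 ± 0.30) and Pfkfb3 (1.92 ± 0.70) were named, of 15 members with 13 positive, 0 adjusted over the list alone, and all those named turned negative with adipocyte scaling. Thermogenic adipocyte genes rose (median 1.26, camera adjusted p = 0.00193 preset, 0.473 estimated), though the median turned to -0.62 with adipocyte scaling. Otop1 (3.63 ± 1.18), Cox7a1 (1.85 ± 0.70) and Tmem26 (1.73 ± 0.68) were named, of 14 members with 12 positive, 0 adjusted over the list alone, and Cox7a1 and Tmem26 turned negative with adipocyte scaling. The thermogenic adipocyte median was 2.17 with quantile normalization and 2.81 without F-L replicate 2. Ucp1 was at 0.0228 and 0.0252 CPM in F-H-L and 0.0901 and 0.0537 CPM in F-L, too few counts for a fold change.

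Mitochondrial lists of nuclear genes rose too. Fatty acid oxidation genes rose (median 1.25, camera adjusted p = 1.4e-08 preset, 0.473 estimated), though the median turned to -1.19 with adipocyte scaling. Eci1 (1.24 ± 0.29), Cpt1a (1.31 ± 0.33) and Acadvl (1.42 ± 0.38) were named, of 19 members with 18 positive, 8 adjusted over the list alone, and all those named turned negative with adipocyte scaling. The fatty acid oxidation median was 1.96 without F-L replicate 2. Nuclear-encoded oxidative phosphorylation genes rose (median 0.62, camera adjusted p = 2.1e-06 preset, 0.473 estimated). Sdhd (0.89 ± 0.25), Cyc1 (0.87 ± 0.26) and Atp5o (0.91 ± 0.28) were named, of 32 members with 28 positive, 0 adjusted over the list alone, and all those named turned negative with adipocyte scaling. The nuclear-encoded oxidative phosphorylation call ended with adipocyte scaling (median -2.27, adjusted p = 0.397). Branched-chain amino acid breakdown genes rose (median 0.92, camera adjusted p = 3.4e-07 preset, 0.473 estimated). Auh (1.28 ± 0.30), Pccb (1.22 ± 0.30) and Mccc2 (1.14 ± 0.29) were named, of 19 members with 18 positive, 4 adjusted over the list alone, and all those named turned negative with adipocyte scaling. The branched-chain amino acid breakdown call ended with adipocyte scaling (median -1.58, adjusted p = 0.0852). Mitochondrially encoded transcripts were not called (median 0.40, camera adjusted p = 0.0624), but camera called them higher with no low-count filter, without F-H replicate 1 or 2, without F-H-L replicate 2 or with the epididymis covariate (medians of 0.46 to 0.74, adjusted p of 4.0e-05 to 0.0440).

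Immune lists were higher in F-H-L than in F-L. Macrophage markers rose (median 1.37, camera adjusted p = 2.7e-08 preset, 0.473 estimated), though the median turned to -1.02 with adipocyte scaling. Itgax (2.89 ± 0.38), Tyrobp (1.82 ± 0.39), Cd68 (1.55 ± 0.47) and Adgre1 (1.38 ± 0.70) were named, of 20 members with 19 positive, 2 adjusted over the list alone, and Tyrobp, Cd68 and Adgre1 turned negative with adipocyte scaling. The macrophage median was 2.17 without F-L replicate 2. Lipid-associated macrophage genes rose (median 1.53, camera adjusted p = 2.2e-08 preset, 0.227 estimated), though the median turned to -1.07 with adipocyte scaling. Trem2 (1.72 ± 0.29), Spp1 (5.48 ± 1.02) and Mmp12 (4.52 ± 0.87) were named, of 17 members with 16 positive, 7 adjusted over the list alone, and Trem2 turned negative with adipocyte scaling. This was again the only list to pass by fry (adjusted p = 0.0208). Cytokine and chemokine genes rose (median 1.80, camera adjusted p = 1.6e-05 preset, 0.473 estimated), though the median turned to -0.64 with adipocyte scaling. Saa3 (4.46 ± 1.01), Ccr2 (1.90 ± 0.55), Cxcl12 (0.88 ± 0.28) and Ccl2 (2.00 ± 1.08) were named, of 24 members with 23 positive, 0 adjusted over the list alone, and Ccr2 and Cxcl12 turned negative with adipocyte scaling. The cytokine median was 1.10 without F-L replicate 1, 1.09 without F-H-L replicate 1 and 1.10 with the epididymis covariate. Interferon response genes rose (median 1.29, camera adjusted p = 8.1e-06 preset, 0.473 estimated), though the median turned to -1.23 with adipocyte scaling. Rsad2 (2.07 ± 0.50), Ifit3 (1.89 ± 0.62) and Xaf1 (1.31 ± 0.44) were named, of 19 members with 19 positive, 0 adjusted over the list alone, and all those named turned negative with adipocyte scaling.

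Lymphocyte and antigen presentation lists followed. MHC class II and dendritic cell genes rose (median 1.55, camera adjusted p = 3.6e-04 preset, 0.524 estimated), though the median turned to -1.17 with adipocyte scaling. H2-DMb1 (2.31 ± 0.63), H2-DMb2 (2.41 ± 0.78) and Batf3 (1.66 ± 0.63) were named, of 17 members with 16 positive, 0 adjusted over the list alone, and all those named turned negative with adipocyte scaling. The MHC class II median was 0.86 with the epididymis covariate. T and NK cell markers rose (median 1.82, camera adjusted p = 3.8e-04 preset, 0.561 estimated), though the median turned to -1.26 with adipocyte scaling. Prf1 (4.55 ± 1.39), Klrb1c (2.38 ± 0.85) and Cd247 (2.09 ± 0.78) were named, of 20 members with 18 positive, 0 adjusted over the list alone, and Klrb1c and Cd247 turned negative with adipocyte scaling. The T and NK cell median was 0.88 with the epididymis covariate. B cell and plasma cell markers rose (median 1.33, camera adjusted p = 0.00246 preset, 0.524 estimated), though the median turned to -1.52 with adipocyte scaling. Ighd (3.15 ± 0.67) and Cd79b (2.15 ± 0.79) were named, of 16 members with 14 positive, 0 adjusted over the list alone, and Cd79b turned negative with adipocyte scaling. Mast cell markers (median 0.65, camera adjusted p = 0.111) and neutrophil markers (median 1.11, camera adjusted p = 0.0742) were not called, but camera called mast cell markers higher without F-L replicate 2 (median 1.24, adjusted p = 0.0231) and with no low-count filter, with quantile normalization, without F-H replicate 1 or without F-H-L replicate 1 (medians of 0.71 to 0.99, adjusted p of 0.00254 to 0.0475), and neutrophil markers higher with adipocyte scaling (median -0.86, against other genes, adjusted p = 3.6e-04) and with no low-count filter, with quantile normalization, with median-ratio factors, without F-H replicate 1 or 2 or without F-H-L replicate 2 (medians of 0.95 to 1.63, adjusted p of 0.00692 to 0.0492).

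Matrix and vascular lists rose and reproductive-tract lists fell. Extracellular matrix genes rose (median 1.70, camera adjusted p = 2.1e-12 preset, 0.473 estimated), though the median turned to -0.49 with adipocyte scaling. Postn (2.07 ± 0.43), Col6a1 (2.08 ± 0.44), Col6a2 (2.42 ± 0.54) and Col1a1 (1.38 ± 0.33), where Postn encodes periostin, were named, of 26 members with 25 positive, 7 adjusted over the list alone, and Postn, Col6a1 and Col1a1 turned negative with adipocyte scaling. The extracellular matrix median was 1.05 without F-L replicate 1 and 2.67 without F-L replicate 2. Adipose progenitor markers rose (median 1.18, camera adjusted p = 2.2e-04 preset, 0.473 estimated), though the median turned to -1.36 with adipocyte scaling. Ly6c1 (1.66 ± 0.37), Pdgfrb (1.39 ± 0.38) and Cd34 (1.33 ± 0.45) were named, of 14 members with 12 positive, 0 adjusted over the list alone, and all those named turned negative with adipocyte scaling. Endothelial markers rose (median 1.52, camera adjusted p = 1.4e-06 preset, 0.473 estimated), though the median turned to -0.73 with adipocyte scaling. Esam (1.36 ± 0.37), Eng (1.60 ± 0.53) and Tie1 (1.93 ± 0.65) were named, of 12 members with 12 positive, 0 adjusted over the list alone, and all those named turned negative with adipocyte scaling. The endothelial median was 2.54 without F-L replicate 2. Immediate early genes rose (median 0.57, camera adjusted p = 0.00635 preset, 0.473 estimated). Btg2 (1.05 ± 0.24), Junb (0.76 ± 0.24) and Jun (0.87 ± 0.34) were named, of 18 members with 13 positive, 0 adjusted over the list alone, and all those named turned negative with adipocyte scaling. The immediate early median was 1.18 without F-L replicate 2, and the call ended without F-L replicate 1 (median 0.39, adjusted p = 0.0520), with limma on TPM (median 0.36, adjusted p = 0.0611) and with adipocyte scaling (median -2.04, adjusted p = 0.397). Testis germ cell markers fell (median -4.45, camera adjusted p = 1.3e-07 preset, 0.473 estimated). Odf1 (-4.14 ± 0.50), Tssk6 (-4.37 ± 0.77) and Smcp (-4.28 ± 0.80) were named, of 14 members with 14 negative, 12 adjusted over the list alone. The testis germ cell median was -5.45 without F-L replicate 1, -1.40 without F-L replicate 2 and -6.22 with adipocyte scaling. Epididymis epithelium markers fell (median -2.44, camera adjusted p = 0.0324 preset, 0.651 estimated). Crisp4 (-2.49 ± 1.02), Abcb5 (-2.71 ± 1.26) and Rnase9 (-2.75 ± 1.33) were named, of 19 members with 17 negative, 0 adjusted over the list alone. The epididymis epithelium median was -1.42 with quantile normalization and -3.14 without F-L replicate 2, and the test turned without F-L replicate 1, and the call ended without F-L replicate 1 (median -0.68, adjusted p = 0.774), without F-H-L replicate 1 (median -2.55, adjusted p = 0.0803), with no low-count filter (median -2.38, adjusted p = 0.0596), with the RPKM filter of 5 (median -2.83, adjusted p = 0.0565), with median-ratio factors (median -2.53, adjusted p = 0.0610), with adipocyte scaling (median -5.92, adjusted p = 0.162) and with the epididymis covariate (median -0.12, adjusted p = 0.333). Here too that covariate tests nothing. Cholesterol synthesis, mesothelial and muscle markers, the circadian clock, ER stress and cell proliferation were not called (camera adjusted p of 0.0759 to 0.900). Of these, camera called cell proliferation higher without F-L replicate 2 (median 2.27, adjusted p = 7.5e-07) and with no low-count filter, without F-H replicate 1 or 2 or without F-H-L replicate 1 or 2 (medians of 0.08 to 0.17, adjusted p of 0.00204 to 0.0264), cholesterol synthesis higher without F-L replicate 1 or without F-H-L replicate 2 (medians of 0.34 to 0.39, adjusted p of 0.0403 to 0.0468), and ER stress lower with the RPKM filter of 5, with quantile normalization, with limma on TPM or without F-L replicate 2 (medians of -0.97 to -0.52, adjusted p of 0.00509 to 0.0446). Gys1 and Ruvbl2, Cd247 and Pou2f1, Tssk6 and Ndufa13, and Eng and Fpgs overlap, so their counts are uncertain.

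The comparison of F-H-L with F-H addressed how the cycled group differed from continuous high-fat feeding. Macrophage, mast cell, cytokine and lymphocyte lists fell in the cycled group by camera with a preset correlation, while lipogenic, adipocyte and mitochondrial lists rose, and 0 of the 24 list calls held with an estimated correlation (smallest adjusted p 0.0690). Trem2 was at 25.2 and 19.1 CPM in F-H-L and 413 and 417 CPM in F-H (log2 fold change -4.23 ± 0.33, n = 2 per group), and Adgre1 at 75.4 and 43.8 CPM against 1310 and 562 CPM. Fasn was at 5082 and 3944 CPM against 1586 and 1381 CPM, and Retn, which encodes the hormone resistin, at 1171 and 1727 CPM against 204 and 195 CPM. edgeR called 0 of 22289 genes (smallest adjusted p 0.219, 2362 with an unadjusted p under 0.05), and DESeq2 called 1196, 482 higher and 714 lower. On the 4 libraries of both groups alone edgeR called 289 genes, 89 higher and 200 lower. With 3 groups it called 828 without F-L replicate 1, 608 without F-L replicate 2, 1759 with no low-count filter and 18 with adipocyte scaling, which moved the median of all genes to -1.088. Here too 0 members of every list passed over all genes tested.

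Macrophage, mast cell and cytokine lists fell. Macrophage markers fell (median -2.83, camera adjusted p = 2.2e-22 preset, 0.474 estimated). Itgax (-3.64 ± 0.39), Ms4a7 (-3.61 ± 0.45), Cd14 (-2.18 ± 0.29) and Adgre1 (-3.97 ± 0.77) were named, of 20 members with 19 negative, 18 adjusted over the list alone. The macrophage median was -4.08 with adipocyte scaling and -1.96 with the epididymis covariate. Lipid-associated macrophage genes fell (median -2.65, camera adjusted p = 2.4e-18 preset, 0.0690 estimated). Trem2 (-4.23 ± 0.33), Gpnmb (-5.38 ± 0.55) and Lgals3 (-2.93 ± 0.36) were named, of 17 members with 16 negative, 12 adjusted over the list alone. The lipid-associated macrophage median was -3.87 with adipocyte scaling. By fry this list passed (adjusted p = 0.00543) and no other did. Mast cell markers fell (median -2.94, camera adjusted p = 2.5e-06 preset, 0.550 estimated). Cpa3 (-3.47 ± 0.54), Mcpt4 (-3.02 ± 0.52) and Cma1 (-2.98 ± 0.55) were named, of 10 members with 8 negative, 6 adjusted over the list alone. The mast cell median was -4.13 with adipocyte scaling. Cytokine and chemokine genes fell (median -1.78, camera adjusted p = 4.6e-08 preset, 0.550 estimated). Ccl3 (-4.51 ± 0.70), Tnf (-3.18 ± 0.82) and Ccl2 (-1.30 ± 1.06) were named, of 24 members with 24 negative, 1 adjusted over the list alone. The cytokine median was -0.94 without F-H replicate 1, -2.59 without F-H-L replicate 1, -2.95 with adipocyte scaling and -0.85 with the epididymis covariate.

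Lymphocyte lists fell, with values that rested on F-H replicate 1. MHC class II and dendritic cell genes fell (median -2.09, camera adjusted p = 1.8e-05 preset, 0.550 estimated). H2-DMb1 (-2.09 ± 0.62), Cd80 (-2.58 ± 0.83) and Ciita (-2.69 ± 0.96) were named, of 17 members with 15 negative, 0 adjusted over the list alone. The MHC class II median was -0.40 without F-H replicate 1, -2.78 without F-H replicate 2 and -3.39 with adipocyte scaling, and the call ended with the epididymis covariate (median -0.26, adjusted p = 0.361). T and NK cell markers fell (median -2.24, camera adjusted p = 1.2e-04 preset, 0.550 estimated). Foxp3 (-3.68 ± 1.38), Cd4 (-2.29 ± 0.87) and Cd3e (-2.78 ± 1.12) were named, of 20 members with 18 negative, 0 adjusted over the list alone. The T and NK cell median was -1.63 with quantile normalization, -2.98 without F-H replicate 2, -3.59 with adipocyte scaling and -1.61 to -1.21 with limma on RPKM, and the test turned without F-H replicate 1 and with the epididymis covariate, and the call ended without F-H replicate 1 (median -0.003, adjusted p = 0.875) and with the epididymis covariate (median -0.06, adjusted p = 0.856). B cell and plasma cell markers fell (median -1.47, camera adjusted p = 4.5e-05 preset, 0.550 estimated). Cd22 (-4.15 ± 0.83), Jchain (-2.60 ± 0.85) and Igkc (-2.82 ± 1.09) were named, of 16 members with 15 negative, 1 adjusted over the list alone. The B cell median was -0.43 without F-H replicate 1 and -2.78 with adipocyte scaling, and the call ended with the epididymis covariate (median -0.46, adjusted p = 0.0629). Interferon response genes were not called (median -0.09, camera adjusted p = 0.359), but camera called them without F-H replicate 1 (median 0.66, adjusted p = 0.00557), without F-H-L replicate 1 (median -0.70, adjusted p = 0.00814), with the epididymis covariate (median 0.79, adjusted p = 6.0e-04) and without F-H replicate 2 (median -0.61, adjusted p = 1.1e-04).

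Stress, growth and matrix lists fell and endothelial markers rose. Immediate early genes fell (median -1.29, camera adjusted p = 1.2e-09 preset, 0.474 estimated). Atf3 (-4.19 ± 0.65), Junb (-1.49 ± 0.24) and Zfp36 (-1.33 ± 0.23) were named, of 18 members with 18 negative, 4 adjusted over the list alone. The immediate early median was -2.48 with adipocyte scaling. Cell proliferation genes fell (median -0.86, camera adjusted p = 1.4e-04 preset, 0.550 estimated). Mcm6 (-1.43 ± 0.28), Mcm3 (-1.43 ± 0.29) and Pcna (-1.34 ± 0.34) were named, of 23 members with 23 negative, 2 adjusted over the list alone. The cell proliferation median was -2.15 with adipocyte scaling, and the call ended with the epididymis covariate (median -0.02, adjusted p = 0.196). Extracellular matrix genes fell (median -0.56, camera adjusted p = 0.00204 preset, 0.603 estimated). Timp1 (-2.08 ± 0.47), Mmp2 (-1.97 ± 0.56), Mmp14 (-1.23 ± 0.35) and Col1a1 (-0.55 ± 0.32) were named, of 26 members with 18 negative, 0 adjusted over the list alone. The extracellular matrix median was -1.75 with adipocyte scaling. ER stress and unfolded protein response genes fell (median -0.34, camera adjusted p = 0.0202 preset, 0.550 estimated). Creld2 (-1.08 ± 0.32), Ddit3 (-0.68 ± 0.36) and Sdf2l1 (-1.21 ± 0.65) were named, of 17 members with 14 negative, 0 adjusted over the list alone. The ER stress median was -1.56 with adipocyte scaling, and the call ended without F-H replicate 1 (median -0.23, adjusted p = 0.201) and with quantile normalization (median -0.26, adjusted p = 0.0589). Endothelial markers rose (median 0.83, camera adjusted p = 0.00301 preset, 0.550 estimated). Esam (1.06 ± 0.37), Egfl7 (1.21 ± 0.46) and Cldn5 (1.77 ± 0.85) were named, of 12 members with 12 positive, 0 adjusted over the list alone, and Esam turned negative with adipocyte scaling. The endothelial call ended with adipocyte scaling (median -0.30, adjusted p = 0.275).

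Adipocyte and lipid lists rose, beside an adipocyte median of 1466 and 1739 CPM in F-H-L. De novo lipogenesis genes rose (median 1.24, camera adjusted p = 7.3e-06 preset, 0.474 estimated). Aacs (1.71 ± 0.31), Elovl6 (1.82 ± 0.40), Mlxipl (1.12 ± 0.32) and Fasn (1.61 ± 0.75), where Mlxipl encodes the carbohydrate-sensing factor ChREBP, were named, of 18 members with 18 positive, 2 adjusted over the list alone, and Mlxipl turned negative with adipocyte scaling. The de novo lipogenesis median was 0.04 with adipocyte scaling. Adipocyte identity and hormone genes rose (median 0.96, camera adjusted p = 0.00171 preset, 0.603 estimated). Cfd (2.92 ± 0.71), Retn (2.86 ± 0.94), Adig (1.47 ± 0.55), Lep (0.79 ± 1.08) and Adipoq (0.99 ± 1.08) were named, of 20 members with 19 positive, 0 adjusted over the list alone. Lipolysis genes rose (median 0.84, camera adjusted p = 0.0449 preset, 0.717 estimated). G0s2 (1.37 ± 0.59), Mgll (1.07 ± 0.49) and Adora1 (0.98 ± 0.46) were named, of 16 members with 14 positive, 0 adjusted over the list alone, and Mgll and Adora1 turned negative with adipocyte scaling. The lipolysis call ended with limma on RPKM (median 0.82, adjusted p = 0.0597), with limma on TPM (median 0.79, adjusted p = 0.0544) and with adipocyte scaling (median -0.34, adjusted p = 0.462). Insulin action and glucose uptake genes rose (median 0.62, camera adjusted p = 0.0134 preset, 0.550 estimated). Gys1 (0.88 ± 0.35), Slc2a4 (1.39 ± 0.62) and Akt2 (0.62 ± 0.29) were named, of 15 members with 14 positive, 0 adjusted over the list alone, and Gys1 and Akt2 turned negative with adipocyte scaling. The insulin action call ended with adipocyte scaling (median -0.58, adjusted p = 0.760). Cholesterol synthesis genes rose (median 0.74, camera adjusted p = 0.00309 preset, 0.550 estimated). Mvk (1.25 ± 0.28), Fdft1 (1.01 ± 0.27) and Insig1 (1.16 ± 0.41) were named, of 22 members with 18 positive, 0 adjusted over the list alone, and Fdft1 turned negative with adipocyte scaling. The cholesterol synthesis call ended with adipocyte scaling (median -0.41, adjusted p = 0.521) and with the epididymis covariate (median 0.44, adjusted p = 0.185). Thermogenic adipocyte genes were not called (median -0.16, camera adjusted p = 0.483). Ucp1 had 1 and 1 counts in the F-H-L libraries and 95 and 238 in the F-H libraries.

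Mitochondrial lists rose. Nuclear-encoded oxidative phosphorylation genes rose (median 0.42, camera adjusted p = 4.5e-05 preset, 0.550 estimated). Ndufv1 (0.81 ± 0.27), Uqcrq (0.91 ± 0.31) and Ndufb8 (0.80 ± 0.29) were named, of 32 members with 32 positive, 0 adjusted over the list alone, and all those named turned negative with adipocyte scaling. With adipocyte scaling, the test turned and the call ended (median -0.79, adjusted p = 0.919). Mitochondrially encoded transcripts rose (median 0.81, camera adjusted p = 8.9e-04 preset, 0.550 estimated). mt-Co2 (0.78 ± 0.28), mt-Co3 (0.89 ± 0.34) and mt-Nd6 (0.93 ± 0.39) were named, of 13 members with 13 positive, 0 adjusted over the list alone, and all those named turned negative with adipocyte scaling. The call ended with adipocyte scaling (median -0.31, adjusted p = 0.426). Branched-chain amino acid breakdown genes rose (median 0.75, camera adjusted p = 7.0e-07 preset, 0.550 estimated). Ivd (1.12 ± 0.25), Acadsb (1.01 ± 0.27) and Pccb (1.06 ± 0.30) were named, of 19 members with 18 positive, 0 adjusted over the list alone, and all those named turned negative with adipocyte scaling. The branched-chain amino acid breakdown call ended with adipocyte scaling (median -0.45, adjusted p = 0.433). Fatty acid oxidation genes were not called (median 0.32, camera adjusted p = 0.222), but camera called them higher with no low-count filter or with quantile normalization (medians of 0.35 to 0.36, adjusted p of 0.0241 to 0.0426).

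Reproductive-tract and epithelial lists rose, and their levels differed between the F-H libraries. The median of mesothelial markers was 0.220 and 12.4 CPM in F-H and 11.1 and 14.7 CPM in F-H-L, and that of epididymis markers 0 and 3.17 CPM and 1.28 and 1.89 CPM. Testis germ cell markers rose (median 4.27, camera adjusted p = 4.3e-08 preset, 0.550 estimated). Odf1 (5.69 ± 0.55), Smcp (4.44 ± 0.82) and Prm2 (4.60 ± 1.42) were named, of 14 members with 14 positive, 2 adjusted over the list alone. The testis germ cell median was 4.86 with a replicate block, 5.47 without F-H replicate 2 and 3.18 with adipocyte scaling. With the 1 member without counts in F-H set to its bound, that median was 4.06. Epididymis epithelium markers rose (median 0.18, camera adjusted p = 8.8e-04 preset, 0.550 estimated), though the median turned to -0.87 with adipocyte scaling. Crisp4 (8.10 ± 1.44), Abcb5 (8.38 ± 1.67) and Rnase9 (7.07 ± 1.65) were named, of 19 members with 10 positive, 5 adjusted over the list alone. The epididymis epithelium median was 6.94 with the RPKM filter of 5, 1.59 with a replicate block, 1.20 with the 4 libraries of both groups alone, 8.78 without F-H replicate 2, 0.96 without F-H-L replicate 1, -0.84 without F-H-L replicate 2 and 3.34 to 5.50 with limma on RPKM, and the call ended without F-H replicate 1 (median -0.80, adjusted p = 0.875) and with the epididymis covariate (median -1.91, adjusted p = 0.471). Again that covariate tests nothing. The mean log2 fold change of the epididymis markers was 1.82, far above the median. Mesothelial markers rose (median 0.47, camera adjusted p = 0.0106 preset, 0.599 estimated), though the median turned to -0.52 with adipocyte scaling. Krt18 (3.20 ± 1.68), Krt8 (2.96 ± 1.87) and Krt7 (2.12 ± 1.43), keratins of simple epithelia in general, were named, of 13 members with 10 positive, 0 adjusted over the list alone. The mesothelial median was 1.07 with the RPKM filter of 5, 1.85 with quantile normalization, 1.86 with a replicate block, 6.80 without F-H replicate 2 and 1.36 to 2.71 with limma on RPKM, and the test turned without F-H replicate 1, and the call ended without F-L replicate 1 (median 0.42, adjusted p = 0.0923), without F-H replicate 1 (median -0.44, adjusted p = 0.830), with the 4 libraries of both groups alone (median 0.41, adjusted p = 0.0549) and with the epididymis covariate (median -0.66, adjusted p = 0.535). Neutrophil markers rose (median 1.54, camera adjusted p = 0.0246 preset, 0.550 estimated). Ltf (4.54 ± 0.83), Camp (2.69 ± 1.01) and S100a8 (1.54 ± 0.87) were named, of 11 members with 10 positive, 1 adjusted over the list alone. The neutrophil median was 0.78 with quantile normalization and 0.40 with adipocyte scaling, and the call ended without F-H replicate 2 (median 1.09, adjusted p = 0.127), without F-H-L replicate 1 (median 0.67, adjusted p = 0.157), with limma on RPKM (medians of 0.94 to 1.29, adjusted p of 0.0917 to 0.112) and with limma on TPM (median 1.10, adjusted p = 0.102). Ltf was at 0.991 and 1.72 CPM in F-H and 49.99 and 13.3 CPM in F-H-L. Adipose progenitor and muscle markers and the circadian clock were not called (camera adjusted p of 0.359 to 0.663). Counts are uncertain for the overlapping pairs Gys1 and Ruvbl2, Adora1 and Mybph, Foxp3 and Ccdc22, Ddit3 and Mars, mt-Nd6 and mt-Nd5, and mt-Co3 and mt-Atp6.

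The last comparison set the F-H and F-H-L differences from F-L side by side. The 137 genes called higher in F-H had a median log2 fold change of 3.83 there and of 1.40 in F-H-L against F-L, 135 of them with the same sign. Against F-H, 136 of them had a negative fold change in F-H-L (median -2.52), and 134 lay between F-L and F-H. The 56 genes called lower had medians of -7.95 and -3.08, and 56 lay between F-L and F-H. These genes were selected on the F-H and F-L libraries, which favours F-H-L values between them. Across all genes tested, which are not independent replicates, both sets of log2 fold changes correlated at r = 0.804, beside 0.497 (0.484 to 0.515) in 20 simulations of unchanged groups against shared controls. Their covariance was 4.02, beside a simulated 0.559 (0.531 to 0.604), and part of the excess may come from the F-L libraries, too few to split. edgeR called 0 genes in both comparisons, where 0 were expected, as F-H-L against F-L had no calls (3975 genes at an unadjusted p under 0.05). DESeq2 called 1948 genes in the same direction in both, and edgeR called 1881 without F-L replicate 1, 3011 without F-L replicate 2, 3065 with no low-count filter and 3148 with adipocyte scaling.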

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

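Adipocyte scaling, the epididymis covariate and the crossed pairing were chosen after results were seen, the rest before. The 193 genes called in F-H against F-L by edgeR became 871, 977 and 1084 with limma on RPKM and pseudocounts of 1, 0.5 and 0.1, 897 on TPM, 873 with the RPKM filter of 5, 1447 with quantile normalization, 3152 at an adjusted p under 0.1, 6025 with no filter, 6035 with DESeq2 and 3526 with adipocyte scaling. edgeR called 0 with median-ratio factors (unadjusted p under 0.05 in 6429 genes), robust empirical Bayes (6392), the 4 libraries of both groups alone (4614) and the epididymis covariate (2159), the smallest adjusted p with all 6 libraries and TMM factors being 0.0448. Leaving out 1 library gave 0 (any F-H or F-H-L library) to 5799 genes (F-L replicate 2), and 4474 without F-L replicate 1. The 0 genes of F-H-L against F-L became 3910 with no filter, 2444 with DESeq2, 6290 with adipocyte scaling, and 0 to 3508 with 1 library left out (2084 without F-L replicate 1). In F-H-L against F-H they became 1759, 1196, 18, 289 on the 4 libraries of both groups alone, and 0 to 828 with 1 library left out (608 without F-L replicate 2). The 0 shared calls became 3065 with no filter, 1948 with DESeq2, 3148 with adipocyte scaling, and 0 to 3011 with 1 library left out (1881 without F-L replicate 1). A library left alone in its group is assumed to vary like the others, and the cause was not tested.

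With the replicate number as a block, edgeR called 0, 0 and 0 genes in the order of the report (unadjusted p under 0.05 in 5262, 2889 and 2054), and the block changed no list call. A crossed pairing of F-H-L with F-L called 0 genes (2254 at an unadjusted p under 0.05).

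The 19, 21 and 24 lists moved became 0, 0 and 0 by camera with an estimated correlation and 1, 1 and 1 by fry, which does not compare a list with other genes. Over the 64 list results and alternatives, 1074 values kept the test's direction and call, 191 lost the call and 6 turned. Adipocyte scaling turned the medians of 3, 18 and 9 higher lists, which is not counted. limma on RPKM or TPM kept the call but moved the median by over 1.5-fold in 19 of 64. With 1 library left out, medians ran from -0.31 to 3.04 for adipocyte genes in F-H against F-L, -3.14 to -0.68 for epididymis markers in F-H-L against F-L, -2.98 to -0.003 for T and NK cell markers and -0.44 to 6.80 for mesothelial markers in F-H-L against F-H. The tests turned without F-L replicate 1 (-0.31 and -0.68) and without F-H replicate 1 (T and NK -0.003, mesothelial -0.44). In F-H-L against F-H, T and NK cell markers also turned with the epididymis covariate (-0.064), and oxidative phosphorylation with adipocyte scaling (-0.79). The cause was not tested.

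Of the 4483 values of named genes, 3602 kept direction and side of the threshold, 585 newly passed, 222 no longer passed and 74 turned. With 1 library left out, Adipoq in F-H against F-L ran from -0.45 to 3.24 and Fasn from -0.89 to 1.11. The others turned with adipocyte scaling, which lowered genes unequally and tests nothing for its list members Slc2a4, Lep and Adipoq. These log2 fold changes included, in F-H against F-L, Prkaca -0.68, Acadvl -0.23, Hadha -0.48, Pdgfra -0.61, Tek -0.14 and Mcm3 -0.06. In F-H-L against F-L they included Slc2a4 -0.48, Slc25a1 -0.06, Gpd1 -0.36, Prkaca -1.43, Mgll -1.16, Gys1 -1.10, Akt2 -1.66, Pfkfb3 -0.10, Eci1 -1.52, Cpt1a -1.30, Acadvl -1.12, Sdhd -1.99, Cyc1 -2.03, Atp5o -1.92, Auh -1.37, Pccb -1.47, Mccc2 -1.57, Cox7a1 -0.52, Tmem26 -0.99, Tyrobp -0.82, Cd68 -0.88, Trem2 -1.30, Ccr2 -0.56, Cxcl12 -2.13, Rsad2 -0.28, Ifit3 -0.65, Xaf1 -1.29, H2-DMb1 -0.25, H2-DMb2 -0.13, Batf3 -1.13, Klrb1c -0.63, Cd247 -0.39, Cd79b -1.07, Postn -0.50, Col6a1 -0.45, Ly6c1 -0.88, Pdgfrb -1.28, Cd34 -1.12, Esam -1.39, Eng -0.68, Tie1 -0.31, Btg2 -1.76, Junb -2.19, Jun -1.75, Fasn -0.67, Adgre1 -0.81 and Col1a1 -1.44. In F-H-L against F-H they included Mlxipl -0.10, Mgll -0.10, Adora1 -0.13, Gys1 -0.31, Akt2 -0.58, Ndufv1 -0.41, Uqcrq -0.34, Ndufb8 -0.43, mt-Co2 -0.40, mt-Co3 -0.26, mt-Nd6 -0.21, Ivd -0.07, Acadsb -0.17, Pccb -0.13, Fdft1 -0.15, Esam -0.11, Lep -0.33 and Adipoq -0.15.

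Depth was not the limit for abundant genes, as 3 counts equal at most 0.0754 CPM, but genes with 1 to 3 counts in a group, such as Defb38, give no stable fold change. Robust empirical Bayes was not run for the lists, since camera here takes no such setting, and no reads needed recovery from the RPKM, since counts were deposited.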

Other observations

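The tests of the fresh testis and epididymis lists were set before their values were seen, and all other tests in this part were chosen only after the results were seen. Reproductive-tract transcripts differed between the libraries of F-L and between those of F-H. Reads of F-L replicate 1 crossing into other libraries would keep 1 ratio for all epididymis genes, but over 8 genes the log2 ratios spanned at least 3.26 and up to 12.26, which argues against crossing as the whole cause. This rests on Lcn5 and Spint4 (-14.23 and -11.27 in F-L replicate 2), while the other 6 genes lay at -1.98 to -2.84 there, near 1 ratio as crossing would give. Testis tissue in the F-L replicate 2 sample is a candidate source: 19 of 20 genes of a fresh testis list (95%) were highest there with at least 8 times the F-H mean, 4 of the 20 being at 1 CPM or more in both F-H libraries. Epididymis tissue in F-L replicate 1 is another: 14 of 18 genes of a fresh list (77.8%) were highest there on the same terms, 1 being at 1 CPM or more in both F-H libraries, and neither fresh list shares a gene with the fixed lists. 3 of the 18 (Spag11b, Teddm1a and Defb25, at 12.9, 4.55 and 2.23 CPM) were highest in F-H replicate 2, where Serpina1f was at 158 CPM against 1156 CPM in F-L replicate 1, so that this source does not cover all epididymis genes. An effect of diet on these transcripts stays open and was not tested.

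Macrophage genes were higher in F-H than in F-L. Dilution of fat RNA by reproductive-tract RNA in F-L would raise all fat-only lists alike. The macrophage median exceeded the endothelial one by 3.52 in log2 (95% bootstrap interval over genes, not libraries, 3.06 to 4.04). As added tissue may bring endothelial RNA, this gap cannot exclude dilution. The macrophage median, 4.24, was 3.05 with adipocyte scaling and 3.72 without F-H replicate 1, which was not its whole source. A high-fat diet effect and dilution may both remain and were not separated here.

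Lipogenic genes were higher in F-H-L than in F-H. The lipogenesis median exceeded the adipocyte one by 0.27 (95% bootstrap interval over genes -0.29 to 0.75). For these genes, a larger adipocyte share and a change within adipocytes cannot be told apart, as the interval includes 0 even without library spread. An effect of recent diet weeks stays open as untested.

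Further lists were given values after the data had been examined. Of 8 Leydig cell steroid genes, 7 were highest in F-L replicate 2, where Insl3 was at 409 CPM, and 2 were at 1 CPM or more in both F-H libraries. Of 15 multiciliated cell genes, 8 were highest in F-L replicate 2 and 7 in F-H-L replicate 1, where Foxj1 was at 76.9 CPM, and 4 were at 1 CPM or more in both F-H libraries. The 24 lysosome genes had median log2 fold changes of 1.80, 0.56 and -1.08 in the order of the report, with 20, 18 and 1 positive, and 4 of them belong to a fixed list. The 14 complement genes had medians of 2.41, 1.19 and -1.40, with 13, 13 and 1 positive, and 3 of them belong to a fixed list. The fresh testis list had medians of -6.84, -4.74 and 1.90 and the fresh epididymis list of -6.21, -2.82 and 2.95.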
